A study of Homo sapiens with 9 samples.

How the data were processed

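Total RNA of LF1 lung fibroblasts was depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols, from proliferating, early senescent and late senescent cells, with 3 libraries each. The values are raw counts per gene, which the authors deposited in 1 table with a column per library and genes named by NCBI Gene number. Reads were aligned to hg38 with HISAT2 2.0.5 and counted with featureCounts of Subread 1.4.6, per the submitters' processing notes. The annotation used for counting, its strand setting and its treatment of reads that match several places were not given in the sources used here, so counts of near-identical genes (histones, interferon alpha genes, HLA genes, protocadherins with shared exons, 7SL) and of overlapping genes are uncertain. Low counts were mostly even: genes with a value of 2 were 3.12 to 4.17 times as many as genes with a value of 1 in the 9 libraries, as when both mates of a read pair are counted.

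Gene symbols came from a RefSeq table of GRCh38.p14, which matched 27745 of 28395 numbers; 650 were unmatched. Exon lengths and strands came from GENCODE v29. Each column was tied to its sample by name, and groups and replicate numbers came from the labels. No pair of libraries within a state was identical or within sampling noise (chi-square per degree of freedom over genes 30.7 to 205).

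Genes were kept with edgeR's filterByExpr (minimum count 10), which left 17602 and removed 10793. Libraries were scaled by the trimmed mean of M values (TMM), and 1 model with the 3 groups was fitted to all 9 libraries with edgeR 4.0.16 (glmQLFit, robust, 6 residual degrees of freedom; R 4.3.3). The 3 comparisons were tested two-sided with the quasi-likelihood F test, and p-values were adjusted by Benjamini and Hochberg over the tested genes. A gene is called at an adjusted p under 0.05. Standard errors come from the same fit, and levels are CPM, counts relative to the library total scaled by TMM. Levels of XIST and Y-linked genes are left out.

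For gene groups, 33 lists were written before the data were examined, as were the comparisons, the rule for named genes and all but 2 of the alternatives. Each list was tested against the other genes with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 33 lists. The test was repeated with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. The counts of called members were also adjusted over the list alone. The lists cover interferon ligands, stimulated genes and signalling, nucleic acid sensing, LINE-1 restriction, the senescence secretome and markers, division and repair, p53 and NF-kB targets, matrix, contractile and lysosomal genes, metabolism, translation and stress, developmental genes, retroelement-derived genes and markers of other cell types. Genes are named by a fixed rule. For each comparison it takes the 8 largest rises and the 8 largest falls among called genes with a mean of at least 2 log2 CPM and no overlap of the groups' CPM, passing over unnamed loci, small and antisense RNA, XIST and Y-linked genes. It adds 39 genes fixed by name, and per list up to 2 called rises and 2 called falls with a mean of at least 1 log2 CPM, or else the member with the highest mean. Results of some genes that the rule picked are not reported here. Genes outside it (FN1, MIR31HG, CTAG2 and those of small structural RNA) were chosen after their values were seen.

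The steps were tested on simulated counts for all 17602 genes, with 200 genes changed. In early senescent against proliferating cells 32.8% of 1.5-fold, 59.7% of 2-fold and 80.3% of 4-fold changes were recovered, with 10 unchanged genes called. In late senescent against proliferating cells the shares were 20.9%, 56.7% and 75.8%, with 6, and in late against early senescent cells 20.9%, 47.8% and 81.8%, with 5. Camera gave an unadjusted p under 0.05 for 1%, 1.4% and 1% of 500 random lists. The simulated genes were independent of each other, so this does not test the preset correlation for lists whose genes move together.

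Alternatives were other scalings (size factors by relative log expression, RLE, upper quartile, library totals), DESeq2 1.42.0, limma-voom, no filter, a mean of at least 1 CPM, an adjusted p of 0.01, edgeR's test against a 1.5-fold change, a fit of only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. Counts halved and rounded up, and a fit without genes of small structural RNA, were added after seeing the data. Overlap between comparisons with the same controls was set against 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9.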

Results

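Gene expression was measured by total RNA sequencing in LF1 cells, a strain of normal diploid human lung fibroblasts that divides a limited number of times in culture and then enters replicative senescence, a lasting arrest of division. The labels also call the cells ES-derived without saying what the abbreviation stands for. The design covered 3 states with 3 libraries each: proliferating cells of early passage, early senescent cells 8 weeks after entry into senescence and late senescent cells 16 weeks after entry. The stated purpose was to follow gene expression and the induction of type I interferon, the antiviral cytokine family, across these states, under a title that names derepression of LINE-1, a retrotransposon that copies itself through reverse transcription. The values are counts per gene, so transcripts of the LINE-1 elements themselves were not analysed here.

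Total counts were 96910685, 124487670 and 102107637 in proliferating replicates 1, 2 and 3, 111612445, 98174663 and 103321888 in early senescent replicates and 82043099, 81545020 and 91055153 in late senescent replicates. A gene with 0 counts in a library could still have lain at up to 0.0212 to 0.0381 CPM, the level of 3 counts in these libraries, and higher if both mates of a read pair were counted; such floors cover counting error only. Spearman correlations across genes, which are not independent replicates, were 0.975 to 0.982 between libraries of a state and 0.936 to 0.968 between states. Nothing in the labels says that the 3 libraries of a state came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Small structural RNA (7SL of the signal recognition particle, 7SK, RNase P RNA, snRNA, snoRNA and similar) took 7.38 ± 0.79% of counts in proliferating, 7.34 ± 0.39% in early senescent and 16.1 ± 2.0% in late senescent libraries (mean ± SD, n = 3). 7SL made up most of it, with 5.35 ± 0.73%, 5.52 ± 0.43% and 11.4 ± 1.8%. In late senescent replicate 2, snoRNA alone took 2.01% of counts, against 0.538% and 0.373% in the other late libraries. Genes with at least 1 count numbered 19593 ± 226, 19425 ± 126 and 20663 ± 440. Of 28395 genes in the table, 17602 were tested. Log2 fold changes below are given ± standard error and levels as CPM, mean ± SD (n = 3).

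The first comparison asked what differed between early senescent and proliferating cells. Mitosis and DNA replication genes fell, and the inhibitor genes CDKN2A, CDKN1A and CDKN2B rose. MKI67 (NCBI Gene 4288, chromosome 10, 128096659 to 128126423 in hg38), the antigen used to mark dividing cells, fell from 349.7 ± 6.07 to 0.728 ± 0.191 CPM, a log2 fold change of −8.90 ± 0.18 (adjusted p = 7.78e-11). CDKN2A (NCBI Gene 1029, chromosome 9, 21967752 to 21995324), which encodes the inhibitor p16, rose by 5.14 ± 0.28 on the log2 scale and CDKN1A (NCBI Gene 1026, chromosome 6, 36676463 to 36687332), which encodes p21, by 3.48 ± 0.22. Also higher were 27 of 37 collagen, 18 of 22 contractile, 37 of 44 lysosomal and 33 of 57 secretome genes, though the calls of these 4 lists ended with an estimated correlation. The 2 type I interferon genes that could be tested, IFNA1 and IFNE, gave no call. In all, 11123 of 17602 genes changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 5132 higher and 5991 lower; 3051 were over 2-fold higher and 3061 over 2-fold lower.

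All 74 mitosis genes fell, with a median log2 fold change of −6.90, as did all 61 DNA replication genes, with a median of −3.92. Both lists stood apart from the other genes (camera adjusted p = 1.77e-34 and 5.73e-25; with an estimated correlation, adjusted p = 0.0126 for each). KIF20A, a kinesin of cytokinesis, fell by 8.76 ± 0.18 on the log2 scale. RRM2, a subunit of ribonucleotide reductase, changed by −8.28 ± 0.12, the replication factor MCM10 by −8.18 ± 0.19 and MCM2, a subunit of the replicative helicase, by −4.05 ± 0.17. Of 58 replication-dependent histone genes, 57 fell, with a median of −5.84 (camera adjusted p = 2.99e-24, adjusted p = 0.127 with an estimated correlation), among them H3C8 (−9.34 ± 0.24), H3C2 (−9.07 ± 0.16), H3C3 (−8.32 ± 0.33) and the linker histone H1-5 (−8.44 ± 0.20). These genes are near-identical copies, so counts of single members are uncertain. In homologous recombination and the Fanconi pathway 31 of 32 genes fell (camera adjusted p = 3.54e-15, adjusted p = 0.0687 with an estimated correlation), including POLQ (−6.95 ± 0.20) and EXO1 (−6.67 ± 0.23). DLGAP5, a spindle protein, and PBK, a mitotic kinase, changed by −8.63 ± 0.29 and −8.33 ± 0.29.

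Of 26 arrest and senescence markers, 8 rose and 16 fell. The list includes genes known to rise and genes known to fall in senescence, and its camera test gave adjusted p = 0.203. CDKN2B, which encodes the inhibitor p15, rose by 6.19 ± 0.27 and GLB1, which encodes lysosomal beta-galactosidase, by 1.61 ± 0.07 on the log2 scale. The nuclear lamina gene LMNB1 changed by −6.95 ± 0.21 and the chromatin protein gene HMGB2 by −5.33 ± 0.19. Among 34 p53 target genes, 27 rose and 1 fell (camera adjusted p = 8.86e-10, adjusted p = 0.0126 with an estimated correlation), with GDF15, a secreted stress factor, at 5.52 ± 0.50, TNFRSF10C at 4.64 ± 0.35 and AEN, an exonuclease, as the member that fell (−0.48 ± 0.08).

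Of 57 genes of the senescence-associated secretome, 33 rose and 13 fell, with a median of 1.30 (camera adjusted p = 0.000419, adjusted p = 0.27 with an estimated correlation). IL6 rose from 1.95 ± 0.105 to 239 ± 32.8 CPM (6.94 ± 0.22). IL1A rose by 6.45 ± 0.34, IL1B by 4.66 ± 0.44, CXCL8 by 2.20 ± 0.42, CCL2 by 1.77 ± 0.32 and CCL20 by 8.43 ± 0.41. IGFBP3, a binding protein of insulin-like growth factors, rose by 3.12 ± 0.14. Other members fell, among them the growth factor HGF (−7.03 ± 0.36), IL11 (−5.07 ± 0.15) and the collagenase MMP1 (−2.21 ± 0.21). The stromelysin MMP3, at 0.240 ± 0.104 CPM in proliferating libraries, changed by −1.46 ± 0.44 (adjusted p = 0.0127), a call that ended with limma-voom (adjusted p = 0.124) and without proliferating replicate 1 (adjusted p = 0.0508). Of 28 NF-kB target genes, 19 rose and 3 fell (camera adjusted p = 4.84e-05, adjusted p = 0.252 with an estimated correlation). The adhesion molecule VCAM1 was at 6.76 ± 0.23 and the apoptosis inhibitor BIRC2 at −1.14 ± 0.09.

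Matrix genes mostly rose. Among 37 collagen genes and collagen-modifying enzymes, 27 rose and 6 fell (camera adjusted p = 1.87e-05, adjusted p = 0.27 with an estimated correlation). COL1A1 went from 1455 ± 262 to 8909 ± 1115 CPM (2.61 ± 0.27) and COL3A1 from 1133 ± 61.5 to 10075 ± 1327 CPM (3.15 ± 0.27), while COL12A1 changed by −1.75 ± 0.18. Of 48 matrix glycoproteins and proteoglycans 33 rose, such as MFAP5 (6.10 ± 0.14) and POSTN (4.99 ± 0.35), and 9 fell, such as the laminin chain LAMA1 (−1.61 ± 0.09), with camera adjusted p = 5.51e-06, adjusted p = 0.127 with an estimated correlation. The share of counts from fibronectin (FN1), chosen after its values were seen, was 0.389 ± 0.002% in proliferating, 4.04 ± 0.29% in early senescent and 2.46 ± 0.15% in late senescent libraries. Of 22 contractile and myofibroblast genes 18 rose and 3 fell (camera adjusted p = 3.71e-05, adjusted p = 0.252 with an estimated correlation), with ACTA2, smooth muscle actin, at 2.92 ± 0.10 and SYNPO2 at 5.44 ± 0.21. Of 44 lysosomal genes 37 rose and 6 fell (camera adjusted p = 1.05e-08, adjusted p = 0.0586 with an estimated correlation), with the fucosidase FUCA1 at 4.60 ± 0.20 and the glucuronidase GUSB at −0.77 ± 0.09.

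Most interferon ligand genes had no counts. IFNA1 (NCBI Gene 3439, chromosome 9, 21440439 to 21441316 in hg38) had 10, 13 and 15 counts in proliferating and 19, 12 and 16 counts in early senescent libraries (0.69 ± 0.41, adjusted p = 0.168). IFNE (NCBI Gene 338376, chromosome 9, 21480839 to 21482313) had 46, 78 and 42 counts and 37, 25 and 44 counts (−0.23 ± 0.32, adjusted p = 0.55); it lies inside the span of the non-coding RNA MIR31HG (21454268 to 21559798; chosen after its values were seen) on the same strand, so that reads of either could be counted for the other. IFNB1 had 0 counts in each of the 9 libraries. The median of the tested ligands was 0.23, or −0.12 when libraries were scaled by their totals, and the list gave adjusted p = 0.791. Interferon-stimulated genes went both ways: of 66, 30 rose and 15 fell, with a median of 0.41 (adjusted p = 0.0551), or 24 and 20 with library totals. The adjusted p of this list fell to 0.0463 without proliferating replicate 2 and to 0.0121 without early senescent replicate 3. IFIT2 rose by 2.75 ± 0.26, TRIM22 by 3.38 ± 0.09 and CXCL10 by 2.90 ± 0.72, whereas OAS3 (−2.71 ± 0.24) and USP18 (−2.45 ± 0.25) fell. OAS1 rose by 2.51 ± 0.85 from 6 counts over the 3 proliferating libraries, and IFIT1 by 0.63 ± 0.21. The OAS1 call ended with limma-voom (adjusted p = 0.0657) and without proliferating replicate 2 (adjusted p = 0.0749), 3 (0.0659), early senescent replicate 1 (0.101) or 2 (0.0565). The IFIT1 call ended with library totals (adjusted p = 0.276) and without proliferating replicate 1 (adjusted p = 0.0633), 2 (0.052), 3 (0.0719) or early senescent replicate 1 (0.116). The values were 1.09 ± 0.67 for ISG15, −0.48 ± 0.28 for MX1, 0.85 ± 0.42 for IRF7 and −0.71 ± 0.76 for IFI44L, without a call. Calls appeared for ISG15 without late senescent replicate 2 (adjusted p = 0.0444) and for MX1 with library totals (adjusted p = 0.0272) and without early senescent replicate 1 (adjusted p = 0.0416). An IRF7 call appeared with DESeq2 (adjusted p = 0.0256), upper quartile scaling (0.0498), a replicate block (0.0226), a fit of the 6 libraries compared (0.0172) and without late senescent replicate 2 (adjusted p = 0.027) or 3 (0.031). The value of CXCL10 was 3.75 without proliferating replicate 1, that of OAS1 3.50 without proliferating replicate 1 and that of IFIT1 0.35 without early senescent replicate 1.

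Of 19 interferon receptor and signalling genes, 12 rose and 4 fell (camera adjusted p = 0.0283, adjusted p = 0.339 with an estimated correlation), with the receptor chain IFNGR1 at 1.36 ± 0.13 and the feedback inhibitor SOCS3 at −3.55 ± 0.16. Of 23 nucleic acid sensors and adaptors, 9 rose and 8 fell (adjusted p = 0.772); the median, 0.001, became −0.35 with scaling by library totals. CGAS, the sensor of cytosolic DNA, changed by −1.93 ± 0.17, IFIH1, a sensor of double-stranded RNA, by 2.27 ± 0.30 and the adaptor STING1 by 0.53 ± 0.10, a call that ended with library totals (adjusted p = 0.139). The LINE-1 restriction list, mostly factors reported to restrict LINE-1, had 2 genes higher and 28 lower of 46. Its median was −0.57 (camera adjusted p = 9.08e-05, adjusted p = 0.102 with an estimated correlation). Members that fell included UHRF1 (−5.54 ± 0.28), a factor of maintenance DNA methylation that dividing cells express, and LMNB1. The 2 members that rose were FOXA1, which is not a restriction factor, and the chromatin remodeller ATRX (0.47 ± 0.11). The ATRX call ended with library totals (adjusted p = 0.349). Of the tested members, 6 are also on another list. RB1, FOXA1 and TREX1 were put on this list because the paper of this study names them, so their direction here is not independent evidence. RB1 changed by −0.61 ± 0.13 and FOXA1 by 3.36 ± 0.65 from 0.0499 ± 0.0304 CPM; the FOXA1 value was 3.96 without proliferating replicate 3 and 2.75 without early senescent replicate 3. The exonuclease gene TREX1 was at −0.42 ± 0.20 (adjusted p = 0.0911), with a call with library totals (adjusted p = 0.00723) or a replicate block (0.0166). SAMHD1, a nucleotide hydrolase, changed by −0.59 ± 0.12.

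Among other lists, 14 of 22 MHC class I presentation genes rose and 1 fell (camera adjusted p = 0.000993, adjusted p = 0.146 with an estimated correlation), with HLA-B at 2.90 ± 0.12 and its regulator NLRC5 at −0.52 ± 0.12; HLA genes share reads. No cytosolic ribosomal protein gene of 76 rose and 68 fell, with a median of −0.55 (camera adjusted p = 1.08e-08, adjusted p = 0.222 with an estimated correlation). Of 58 nuclear genes of oxidative phosphorylation 3 rose and 36 fell (camera adjusted p = 0.00158, adjusted p = 0.461 with an estimated correlation), such as NDUFA9 (−0.93 ± 0.07). In the unfolded protein and integrated stress responses 17 of 27 rose and 5 fell (camera adjusted p = 0.000697, adjusted p = 0.339 with an estimated correlation), with TRIB3 at 2.89 ± 0.18 and the chaperone HSPA5 at −0.59 ± 0.08. For cholesterol synthesis the counts were 12 and 7 of 25 (adjusted p = 0.128), or 10 and 10 with library totals. Immediate early and heat shock genes, a list of handling stress, had 6 higher and 13 lower of 30 (adjusted p = 0.279). The largest rises by the fixed rule were TMEM178B (11.96 ± 0.31, from 11 counts over the proliferating libraries), the cytokine receptor chain CSF2RB (11.06 ± 0.69, from 0.0374 ± 0.00851 CPM), cyclin D2 (CCND2, 8.89 ± 0.17) and the calcification inhibitor MGP (8.51 ± 0.61). They were followed by CLSTN2 (8.09 ± 0.83), the tight junction gene CLDN1 (7.68 ± 0.24), the collagen receptor chain ITGA11 (7.64 ± 0.15) and HAPLN1 (7.55 ± 0.60). TMEM178B was at 12.87 without proliferating replicate 1 and CLSTN2 at 8.97 without proliferating replicate 2.

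Camera called 21 of 33 lists in this comparison at its preset correlation, and 4 calls held with an estimated correlation: mitosis, DNA replication, p53 targets and clustered protocadherins. Scaling by library totals lowered the median of all genes by 0.35 on the log2 scale and moved the split to 3596 higher and 8344 lower, that is 30.1% higher against 46.1%; upper quartile scaling raised the median by 0.14. Adjusted over the list alone, the counts were those given for 28 of the 33 lists. The others were 34 and 14 for the secretome, 28 and 1 for p53 targets, 38 and 6 for lysosomal genes, 35 and 6 for protocadherins and 3 and 4 for endothelial markers.

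**Figure D1:**
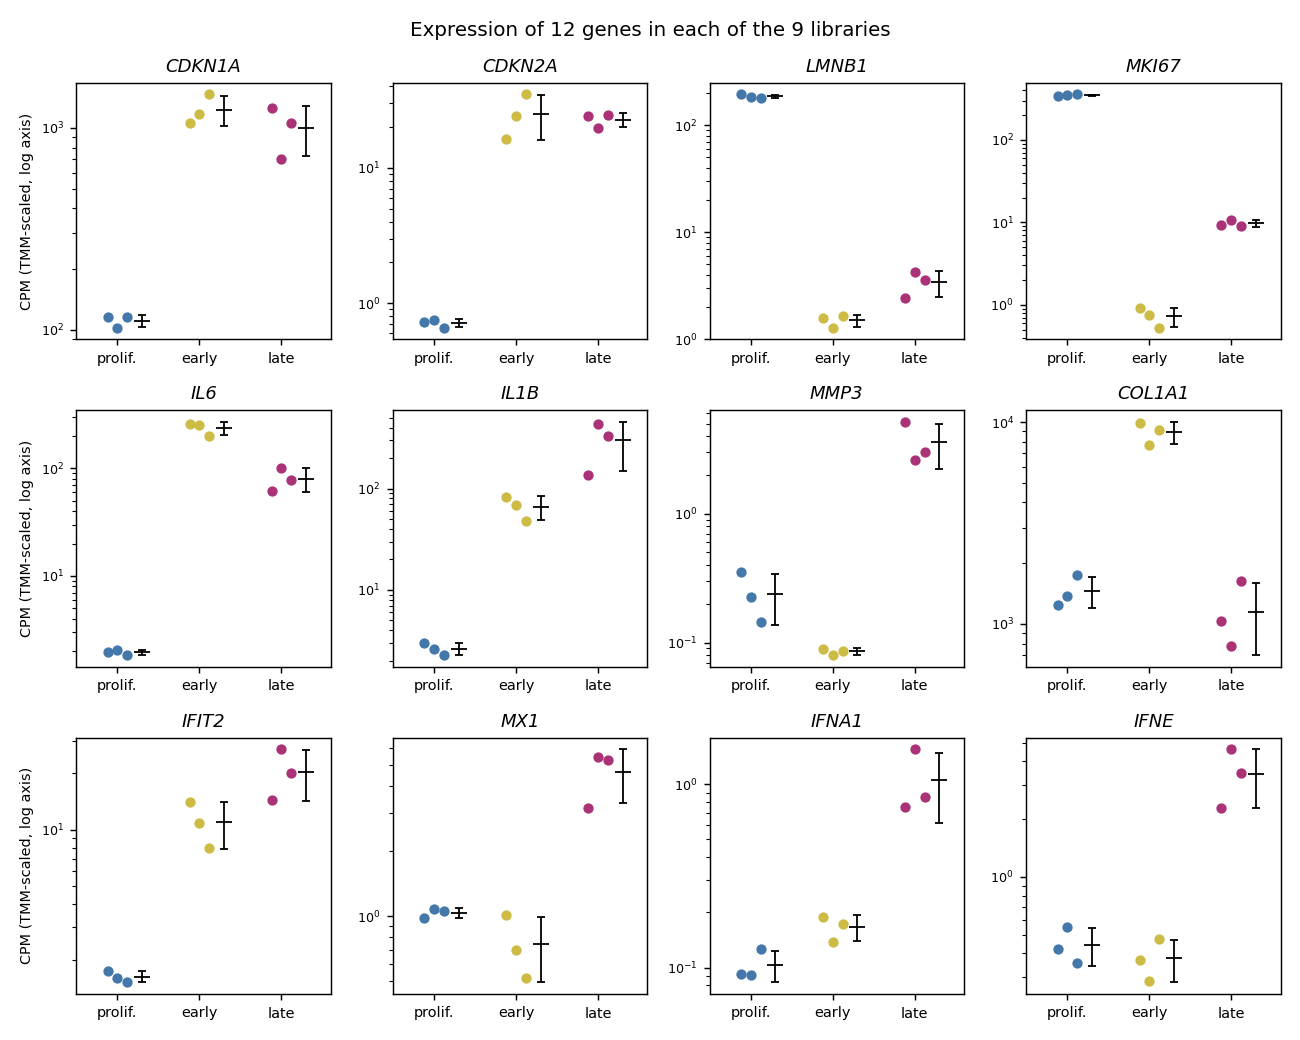
Levels of 12 genes in the 9 libraries, in CPM scaled by TMM on a log axis. Each point is a library, and the black dash and bar are the mean and SD of the 3 libraries of a state; MKI67 and LMNB1 lie far lower in both senescent states, while MMP3, MX1, IFNA1 and IFNE are higher in late than in early senescent libraries.

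The comparison of late senescent with proliferating cells asked how cells differed 16 weeks after entry into senescence. Mitosis and DNA replication genes were lower. Of the secretome genes 39 of 57 were higher and 8 lower, and of the interferon-stimulated genes 43 of 66 and 6, though both list calls ended with an estimated correlation. MKI67 was at 9.69 ± 0.960 CPM, a log2 fold change of −5.17 ± 0.15, and IL1B (NCBI Gene 3553, chromosome 2, 112829751 to 112836779) rose from 2.63 ± 0.348 to 304 ± 154 CPM (6.85 ± 0.48). The interferon genes IFNA1 and IFNE rose by 3.33 ± 0.39 and 2.96 ± 0.32 (adjusted p = 2.4e-05 and 1.17e-05), and the interferon-stimulated gene MX1 by 2.16 ± 0.28. Changed genes numbered 11537, with 5641 higher and 5896 lower; 3755 were over 2-fold higher and 2687 over 2-fold lower. These libraries carried the higher structural RNA share given above, 16.1% against 7.38%.

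All 74 mitosis genes and all 61 DNA replication genes fell, with medians of −5.02 and −3.68 (camera adjusted p = 4.43e-31 and 4.5e-24; with an estimated correlation, adjusted p = 0.012 for each). The mitotic kinases AURKB and TTK changed by −6.00 ± 0.38 and −5.90 ± 0.19, cyclin B1 (CCNB1) by −4.68 ± 0.12 and MCM2 by −3.78 ± 0.17. Of the histone genes 56 of 58 fell (camera adjusted p = 1.03e-23, adjusted p = 0.144 with an estimated correlation), such as H2BC14 (−7.99 ± 0.20), H3C2 (−7.64 ± 0.15) and H1-5 (−7.17 ± 0.19), and of the recombination and Fanconi genes all 32 (camera adjusted p = 2.39e-14, adjusted p = 0.0778 with an estimated correlation), such as BLM (−5.08 ± 0.14). Arrest and senescence markers had 9 higher and 15 lower (adjusted p = 0.175). CDKN2A rose to 22.8 ± 2.79 CPM from 0.712 ± 0.0459 CPM, CDKN1A was at 3.18 ± 0.21, CDKN2B at 5.29 ± 0.26, GLB1 at 1.34 ± 0.07, LMNB1 at −5.77 ± 0.20 and HMGB2 at −4.82 ± 0.19. Of the p53 targets 30 rose and 1 fell (camera adjusted p = 3.51e-09, adjusted p = 0.012 with an estimated correlation), with SPATA18 at 5.19 ± 0.15 and GDF15 at 5.62 ± 0.50.

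Of the secretome genes 39 rose and 8 fell, with a median of 2.26 (camera adjusted p = 1.67e-07, adjusted p = 0.15 with an estimated correlation). IL1A was at 7.04 ± 0.34, IL6 at 5.36 ± 0.20, CXCL8 at 5.09 ± 0.47, CCL2 at 2.97 ± 0.33 and CCL20 at 7.73 ± 0.41. MMP1 rose by 1.65 ± 0.20, MMP3 by 3.91 ± 0.37 and IGFBP3 by 3.18 ± 0.14. Lower members were the chemokine CXCL12 (−3.11 ± 0.39), IL11 (−4.52 ± 0.15) and HGF (−1.98 ± 0.27). Among NF-kB targets 23 rose and 3 fell (camera adjusted p = 5.5e-06, adjusted p = 0.201 with an estimated correlation), with VCAM1 at 6.89 ± 0.23.

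Of the interferon ligand genes, 5 of 17 had counts in each of the 3 late libraries, against 2 in proliferating and 2 in early senescent libraries, and 10, 2 and 3 had any count. Late libraries gained counts in other genes too. Of genes with a known exon length and no counts in proliferating and early senescent libraries, 17% of olfactory receptor genes had counts in a late library. The share was 20.1% for the other such genes. The gain of ligands other than IFNA1 and IFNE was not tested against these shares. IFNA1 held 59, 126 and 77 counts (1.05 ± 0.439 CPM) and IFNE 180, 376 and 314 counts (3.46 ± 1.18 CPM). The IFNA genes are near-identical copies and IFNE overlaps MIR31HG, so both carry that uncertainty. As a list the 2 tested ligands gave adjusted p = 0.0667, and 0.0496 without late senescent replicate 1. Of the interferon-stimulated genes 43 of 66 rose and 6 fell, with a median of 1.04 (camera adjusted p = 2.08e-05, adjusted p = 0.442 with an estimated correlation), or 38 and 11 with library totals. IFIT1 rose from 3.86 ± 0.174 to 10.2 ± 1.83 CPM, IFIT2 by 3.65 ± 0.27 on the log2 scale, TRIM22 by 3.16 ± 0.09 and IFI44L by 2.89 ± 0.64. OAS1 rose by 6.20 ± 0.75 and CXCL10 by 5.92 ± 0.70, from 6 and 13 counts over the proliferating libraries to 1.29 ± 0.340 and 2.24 ± 0.793 CPM. OAS1 was at 7.18 without proliferating replicate 1 and CXCL10 at 6.77 without proliferating replicate 1. USP18 (−1.28 ± 0.24), OAS3 (−0.92 ± 0.22) and PNPT1 (−1.27 ± 0.10) fell. ISG15 (1.25 ± 0.67) and IRF7 (0.38 ± 0.42) gave no call; a call for ISG15 appeared with upper quartile scaling (adjusted p = 0.0489) and without late senescent replicate 2 (adjusted p = 0.00815).

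Interferon receptor and signalling genes had 12 higher and 2 lower (camera adjusted p = 0.0221, adjusted p = 0.359 with an estimated correlation), with IRF1 at 0.97 ± 0.17 and SOCS3 at −2.14 ± 0.15. Nucleic acid sensing genes had 8 higher and 7 lower (adjusted p = 0.898), and their median of 0.19 became −0.02 with scaling by library totals. CGAS was at −2.84 ± 0.18, IFIH1 at 2.30 ± 0.30 and STING1 at 0.19 ± 0.10 (adjusted p = 0.1). A STING1 call appeared with RLE (adjusted p = 0.0304), upper quartile scaling (0.00116), a mean of at least 1 CPM (0.0154), DESeq2 (0.0447) and without late senescent replicate 1 (adjusted p = 0.0483). The LINE-1 restriction list had 9 higher, FOXA1 among them, and 29 lower. Its median was −0.58 (camera adjusted p = 0.00067, adjusted p = 0.144 with an estimated correlation). RB1 was at −0.77 ± 0.13, FOXA1 at 3.42 ± 0.66 (4.01 without proliferating replicate 3), SAMHD1 at −0.45 ± 0.12 (adjusted p = 0.266 with upper quartile scaling) and ATRX at 1.08 ± 0.11. TREX1 was at −0.53 ± 0.20 (adjusted p = 0.0353); the call ended with upper quartile scaling (adjusted p = 0.265), with a mean of at least 1 CPM (0.0907), in a fit of the 6 libraries compared (adjusted p = 0.0527) and without proliferating replicate 2 (adjusted p = 0.0659), 3 (0.132), late senescent replicate 1 (0.108) or 2 (0.1).

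Collagen genes had 21 higher and 5 lower (camera adjusted p = 0.00458, adjusted p = 0.442 with an estimated correlation). COL3A1 rose by 1.98 ± 0.25, while COL1A1 was at −0.34 ± 0.25 (adjusted p = 0.255), with a call without late senescent replicate 3 (adjusted p = 0.0142). Of the matrix glycoproteins 33 rose and 9 fell (camera adjusted p = 6.24e-05, adjusted p = 0.164 with an estimated correlation), with MFAP5 at 4.93 ± 0.13 and the basement membrane gene NID2 at −1.97 ± 0.12. Contractile genes had 9 higher and 5 lower (adjusted p = 0.32), with a median of 0.08 that became −0.13 with scaling by library totals; ACTA2 was at 0.79 ± 0.10 and the calponin CNN2 at −1.23 ± 0.13. Of the lysosomal genes 35 rose and 2 fell (camera adjusted p = 1.58e-08, adjusted p = 0.0638 with an estimated correlation), with CTSO at 2.98 ± 0.17. MHC class I genes had 15 higher and 1 lower (camera adjusted p = 0.0043, adjusted p = 0.194 with an estimated correlation), with the peptidase ERAP2 at 2.26 ± 0.25. Ribosomal protein genes had 0 higher and 70 lower, with a median of −0.83 (camera adjusted p = 9.6e-14, adjusted p = 0.144 with an estimated correlation). Oxidative phosphorylation genes had 0 and 47 (camera adjusted p = 5.66e-08, adjusted p = 0.252 with an estimated correlation), with COX7A2 at −1.17 ± 0.11. The stress response list had 13 higher and 4 lower (camera adjusted p = 0.0218, adjusted p = 0.482 with an estimated correlation), but 22 and 2 with upper quartile scaling and 13 and 7 with library totals, with DNAJB9 at 2.14 ± 0.14. Cholesterol synthesis had 13 and 7 (adjusted p = 0.081, or 15 and 2 with upper quartile scaling) and immediate early and heat shock genes 6 and 17 (adjusted p = 0.0598). Among the largest rises by the fixed rule were TMEM178B (12.38 ± 0.31, or 13.27 without proliferating replicate 1), CSF2RB (11.42 ± 0.69), MGP (10.72 ± 0.62), CCND2 (9.44 ± 0.18), the cadherin CDH10 (8.18 ± 0.36) and PPP4R4 (7.88 ± 0.38).

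Camera called 19 of 33 lists here, and 4 calls held with an estimated correlation, again mitosis, DNA replication, p53 targets and clustered protocadherins. Upper quartile scaling raised the median of all genes by 0.28 on the log2 scale and gave 7360 genes higher and 4364 lower (62.8% higher against 48.9%); library totals lowered the median by 0.21. Adjusted over the list alone, counts were those given for 27 of 33 lists. The others were 44 and 8 for interferon-stimulated genes, 40 and 8 for the secretome, 0 and 57 for histones, 6 and 18 for immediate early and heat shock genes, 1 and 18 for HOX and lung mesenchyme genes and 4 and 8 for ERV-derived genes.

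**Figure D2:**
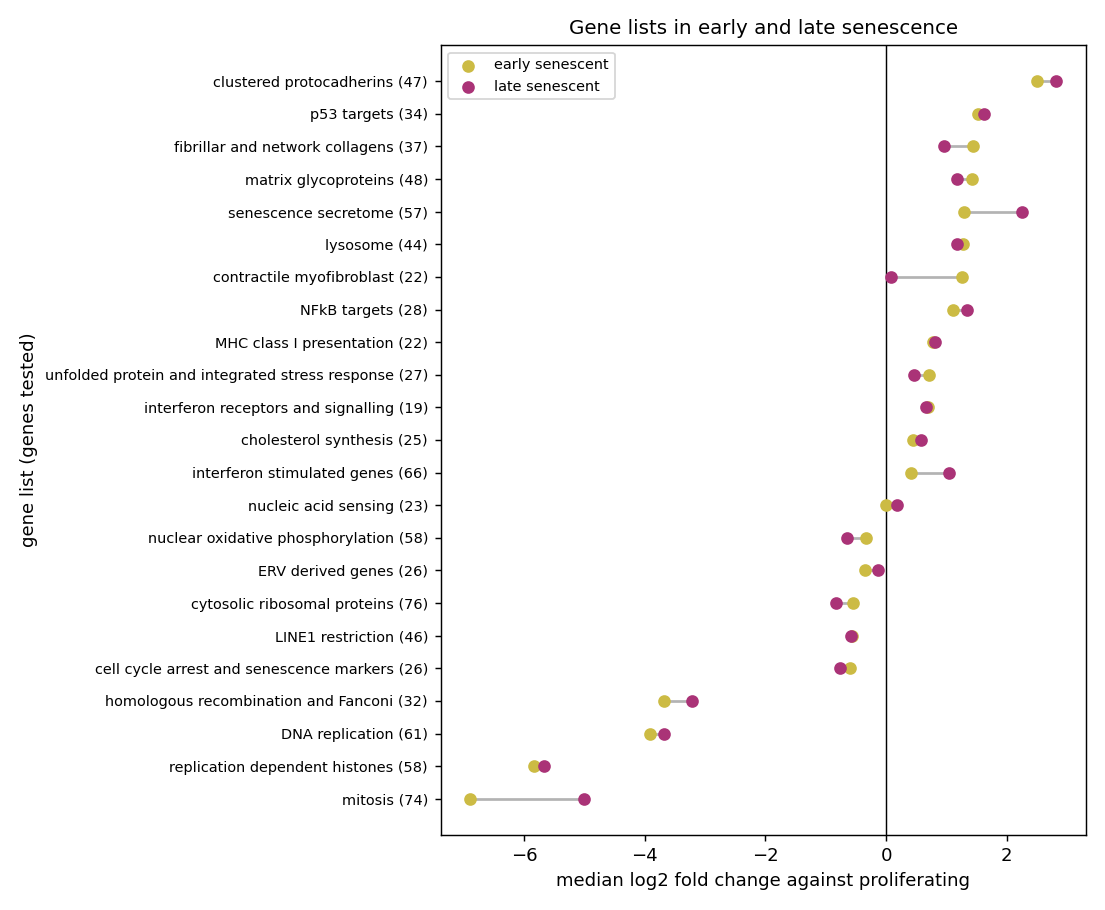
Median log2 fold change against proliferating cells of 23 gene lists with at least 10 tested members, in early and in late senescence. Lists of cell type markers, of HOX and lung mesenchyme genes and of immediate early and heat shock genes are not shown. The mitosis list has the lowest median in early senescence, −6.90, and −5.02 in late senescence; scaling by library totals turns the signs of nucleic acid sensing in both states and of contractile genes in late senescence, and upper quartile scaling that of ERV-derived genes in late senescence.

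The comparison between the senescent states asked what differed between 8 and 16 weeks. The secreted proteases MMP1 and MMP3 and the interferon ligands IFNA1 and IFNE were higher in late senescent cells. So were 30 of 66 interferon-stimulated genes, while 21 of 37 collagen and 16 of 22 contractile genes were lower, though these list calls ended with an estimated correlation. MMP3 (NCBI Gene 4314, chromosome 11, 102835801 to 102843609) was at 0.0856 ± 0.00488 CPM in early and 3.60 ± 1.36 CPM in late senescent libraries, a log2 fold change of 5.37 ± 0.42, and COL1A1 (NCBI Gene 1277, chromosome 17, 50184101 to 50201631) at 8909 ± 1115 and 1147 ± 444 CPM (−2.96 ± 0.27). Of the mitosis genes 64 of 74 were also higher in late than in early senescent libraries, at levels far below those of proliferating cells, and this list call too ended with an estimated correlation. Changed genes numbered 6886, with 3572 higher and 3314 lower; 2297 were over 2-fold higher and 499 over 2-fold lower. The structural RNA share differed between the states, 16.1% in late against 7.34% in early libraries.

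Of the mitosis genes 64 of 74 rose and none fell, with a median of 1.60 (camera adjusted p = 1.59e-24, adjusted p = 0.0797 with an estimated correlation). MKI67 rose by 3.73 ± 0.16, KIF20A by 3.41 ± 0.15 and CCNB1 by 0.96 ± 0.10. Of the DNA replication genes 27 rose and 3 fell (camera adjusted p = 0.000292, adjusted p = 0.291 with an estimated correlation), with CLSPN, a checkpoint mediator, at 2.80 ± 0.18 and RRM2 at 2.61 ± 0.10. Histone genes had 21 higher and 3 lower (camera adjusted p = 0.00276, adjusted p = 0.674 with an estimated correlation), with H3C8 at 2.18 ± 0.23 and H1-1 at −0.94 ± 0.11. Recombination and Fanconi genes had 19 and 1 (camera adjusted p = 3.43e-05, adjusted p = 0.354 with an estimated correlation), with POLQ at 2.33 ± 0.19 and FANCE at −1.02 ± 0.17. Arrest and senescence markers had 6 higher and 6 lower (adjusted p = 0.737); their median of −0.07 became 0.07, with 8 and 3, with upper quartile scaling or library totals. CDKN2B fell by 0.90 ± 0.21 on the log2 scale, while LMNB1 rose by 1.18 ± 0.18. The values were −0.30 ± 0.20 for CDKN1A and −0.15 ± 0.23 for CDKN2A, without a call. HMGB2 was at 0.50 ± 0.16 (adjusted p = 0.0329), a call that ended in a fit of the 6 libraries compared (adjusted p = 0.0656) and without proliferating replicate 2 (adjusted p = 0.054), 3 (0.0508), early senescent replicate 2 (0.0615), late senescent replicate 1 (0.0689) or 3 (0.0639). Its value was 0.30 without early senescent replicate 3. The p53 targets had 5 higher and 5 lower (adjusted p = 0.611), but 15 and 3 with upper quartile scaling or library totals, with SESN2 at −0.90 ± 0.16.

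**Figure D3:**
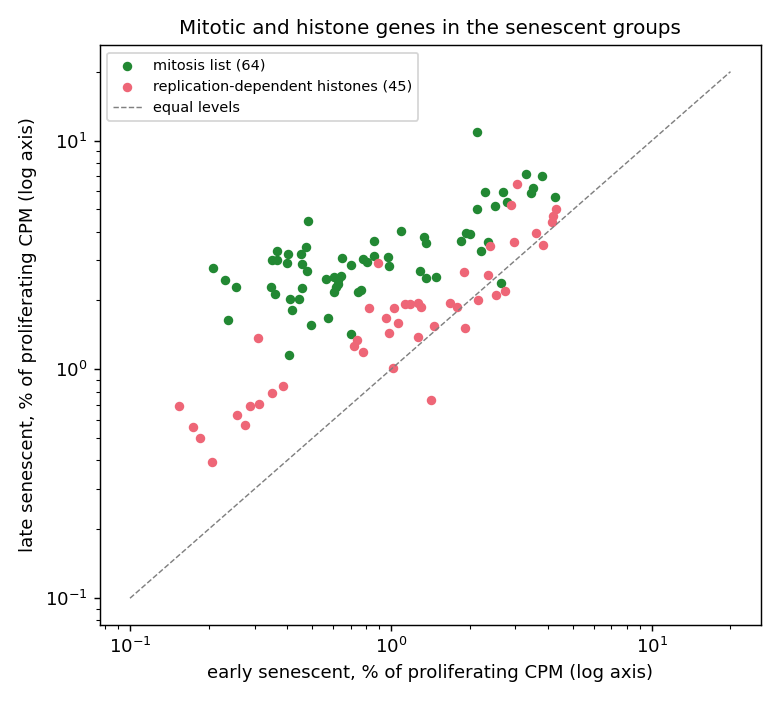
Levels of 64 mitosis genes and 45 replication-dependent histone genes that lay under 5% of their proliferating level in early senescence, as percent of the mean proliferating CPM, early on the horizontal and late on the vertical log axis. The dashed line marks equal levels. Above it lie 63 of the 64 mitosis genes and 38 of the 45 histone genes, and the late levels of the mitosis genes run from 1.15% to 10.9%. Choosing genes by a low early level favours points above the line. Of the whole lists, 64 of 74 mitosis genes were called higher in late than in early senescence. For histone genes 21 of 58 were called higher and 3 lower.

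Of the secretome genes 26 rose and 14 fell, with a median of 0.59 (camera adjusted p = 0.0367, adjusted p = 0.634 with an estimated correlation). Scaling by library totals gave an adjusted p of 0.161, and leaving out proliferating replicate 1 (0.0502), early senescent replicate 1 (0.0614), 2 (0.0594) or 3 (0.0519), or late senescent replicate 2 (0.0539) or 3 (0.114) also ended the call. HGF rose by 5.06 ± 0.34, MMP1 by 3.86 ± 0.22, CXCL8 by 2.88 ± 0.42, IL1B by 2.19 ± 0.38 and CCL2 by 1.20 ± 0.31 (0.79 without late senescent replicate 2). IL6 (−1.57 ± 0.17) and VEGFA (−1.38 ± 0.18) fell. IGFBP3 (0.05 ± 0.13), GDF15 (0.10 ± 0.40) and IL1A (0.59 ± 0.26) gave no call, though IL1A did with upper quartile scaling (adjusted p = 0.0378), with DESeq2 (0.0443) and without late senescent replicate 1 (adjusted p = 0.00623). NF-kB targets had 11 higher and 7 lower (adjusted p = 0.439), or 13 and 4 with upper quartile scaling, with PTGS2, the inducible cyclooxygenase, at 1.72 ± 0.20.

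IFNA1 rose by 2.64 ± 0.38 (adjusted p = 0.000458) and IFNE, which overlaps MIR31HG, by 3.19 ± 0.33 (adjusted p = 5.47e-05), with camera adjusted p = 0.0211, adjusted p = 0.354 with an estimated correlation for the pair as a list. Interferon-stimulated genes had 30 higher and 3 lower of 66, with a median of 0.34 (camera adjusted p = 0.000117, adjusted p = 0.634 with an estimated correlation). MX1 rose by 2.64 ± 0.29, OAS1 by 3.69 ± 0.61, IFI44L by 3.60 ± 0.70, CXCL10 by 3.03 ± 0.57, IFITM1 by 1.93 ± 0.15 and OAS3 by 1.79 ± 0.23, whereas GBP1 (−0.55 ± 0.12) fell. IFIT1 was at 0.77 ± 0.21 (adjusted p = 0.0154), a call that ended without early senescent replicate 2 (adjusted p = 0.0602). IFI44L was at 4.48 without early senescent replicate 1. ISG15 (0.16 ± 0.66) and IRF7 (−0.46 ± 0.42) gave no call. Receptor and signalling genes had 4 higher and 4 lower (adjusted p = 0.754), but 7 and 3 with upper quartile scaling and 6 and 3 with library totals. Sensing genes had 4 and 4 (adjusted p = 0.679), with CGAS at −0.91 ± 0.17 and IKBKE at −0.57 ± 0.12. STING1 was at −0.34 ± 0.10, a call that ended with upper quartile scaling (adjusted p = 0.134), library totals (0.151) or a mean of at least 1 CPM (0.0569) and without early senescent replicate 2 (adjusted p = 0.0539) or late senescent replicate 1 (0.0609). The LINE-1 restriction list had 13 higher and 9 lower (adjusted p = 0.483), but 17 and 2 with upper quartile scaling and 17 and 1 with library totals. HELLS, a chromatin remodeller, was at 0.82 ± 0.15 and DAXX, a histone chaperone, at −0.73 ± 0.08. RB1 (−0.16 ± 0.13), TREX1 (−0.12 ± 0.20), FOXA1 (0.06 ± 0.55) and SAMHD1 (0.15 ± 0.12) gave no call.

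Collagen genes had 4 higher and 21 lower (camera adjusted p = 0.00208, adjusted p = 0.584 with an estimated correlation), or 7 and 18 with upper quartile scaling or library totals, with COL3A1 at −1.17 ± 0.25. Matrix glycoproteins had 8 and 18 (camera adjusted p = 0.0297, adjusted p = 0.568 with an estimated correlation), with LAMA1 at 3.09 ± 0.10 and the proteoglycan HSPG2 at −2.24 ± 0.35. No contractile gene rose and 16 of 22 fell (camera adjusted p = 7.97e-08, adjusted p = 0.291 with an estimated correlation), such as ACTA2 (−2.14 ± 0.10). Ribosomal protein genes had 0 higher and 35 lower (camera adjusted p = 8.9e-08, adjusted p = 0.354 with an estimated correlation), but 1 and 8 with upper quartile scaling and 1 and 10 with library totals, with RPS12 at −0.72 ± 0.12. Oxidative phosphorylation genes had 0 and 26 (camera adjusted p = 1.55e-06, adjusted p = 0.421 with an estimated correlation), but 0 and 7 and 0 and 8 with these 2 scalings. The stress response list had 3 and 12 (camera adjusted p = 0.0203, adjusted p = 0.634 with an estimated correlation), with TRIB3 at −1.77 ± 0.17. Lysosomal genes had 8 and 9 (adjusted p = 0.86), but 15 and 5 and 13 and 4 with the same scalings, which turned the median from −0.01 to 0.13. MHC class I genes had 2 and 7 (adjusted p = 0.472), but 6 and 5 with either scaling. Immediate early and heat shock genes had 5 and 9 (adjusted p = 0.474), but 7 and 6 with either scaling, which turned the median from −0.05 to 0.08 or 0.09. Cholesterol synthesis genes had 5 and 1 (adjusted p = 0.474). The largest rises by the fixed rule were the granule protein SCG2 (6.37 ± 0.49), FGL2 (5.46 ± 0.44), HGF, and PDK4, a kinase that inhibits pyruvate dehydrogenase (5.02 ± 0.30), then RELN (5.02 ± 0.34), the urea transporter SLC14A1 (4.69 ± 0.31), COLEC10 (4.14 ± 0.40) and PRKG2 (4.07 ± 0.16). The largest falls were S100A4 (−3.73 ± 0.39, or −4.44 without late senescent replicate 1), COL1A1, ASS1, an enzyme of arginine synthesis (−2.95 ± 0.26), CRABP2 (−2.88 ± 0.13), SGCD (−2.70 ± 0.28), ITGBL1 (−2.68 ± 0.24), OSCAR (−2.53 ± 0.23) and the desmosomal cadherin DSC3 (−2.53 ± 0.10).

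Camera called 16 of 33 lists in this comparison and no call held with an estimated correlation. Upper quartile scaling gave 4506 genes higher and 1937 lower (69.9% higher against 51.9%) and library totals 4536 and 1931 (70.1%), with the median of all genes 0.14 higher on the log2 scale in each. Adjusted over the list alone, counts were those given for 16 of 33 lists. The others, as higher and lower, were 30 and 4 for interferon-stimulated genes, 3 and 4 for sensing, 27 and 15 for the secretome, 65 and 0 for mitosis, 23 and 3 for histones, 12 and 7 for NF-kB targets, 3 and 7 for MHC class I, 4 and 23 for collagens, 10 and 19 for matrix glycoproteins, 0 and 17 for contractile genes and 8 and 10 for lysosomal genes. They were also 0 and 40 for ribosomal proteins, 5 and 10 for immediate early and heat shock genes, 27 and 3 for protocadherins, 17 and 2 for HOX and lung mesenchyme genes, 5 and 2 for immune markers and 8 and 4 for ERV-derived genes.

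Changes in early and late senescence against the same proliferating cells were then compared. Genes higher in both senescent states numbered 3993, where independent lists of the same sizes would share 1645, and genes lower in both numbered 4626, against 2007. Opposite directions were called for 338 genes, 78 higher early and lower late and 260 lower early and higher late. Both comparisons use the same 3 proliferating libraries. In 20 simulations of unchanged groups against these controls, a mean of 0.05 genes was called in both comparisons (at most 1), against 8957 observed, and the correlation of log2 fold changes across genes was 0.463, against 0.821 observed. The covariance was 2.999 observed and 0.0696 simulated, and 80.5% of genes had the same sign, against 66.5% simulated. The 3 controls could not be split into parts of at least 2 libraries, so part of the excess over independent lists may come from the shared controls. With no gene changed, the simulated number of genes called in both is small by design and does not measure that part. The simulated covariance does carry the shared error of the controls, and it was far under the observed one.

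Marker lists of cell types described the identity of the cells. Fibroblast markers had 11 higher and 1 lower of 16 in early senescence (camera adjusted p = 0.000515, adjusted p = 0.14 with an estimated correlation). The counts were 8 and 3 in late senescence (adjusted p = 0.0711), and 2 and 11 in late against early senescence (camera adjusted p = 0.00138, adjusted p = 0.291 with an estimated correlation). Of the tested members, 7 are on other lists. LUM was at 3.49 ± 0.14 in early and 2.45 ± 0.13 in late senescence, and VIM, an intermediate filament gene, went from 3631 ± 176 CPM in proliferating to 2489 ± 201 and 1818 ± 100.5 CPM. Epithelial markers had 10 higher and 2 lower of 16 in early senescence (camera adjusted p = 0.0123, adjusted p = 0.336 with an estimated correlation). The counts were 8 and 2 in late (adjusted p = 0.0591) and 1 and 3 in late against early senescence (adjusted p = 0.439, with a median that changed sign with library totals or upper quartile scaling). KRT18 went from 132 ± 4.92 to 501 ± 57.1 and 362 ± 46.4 CPM, and CLDN4 from 52.4 ± 8.68 to 0.594 ± 0.199 and 0.841 ± 0.363 CPM. For 8 endothelial markers the counts higher and lower were 3 and 3 in early, 3 and 2 in late and 1 and 1 in late against early senescence, with TEK at 2.25 ± 0.08 in early and 1.74 ± 0.08 in late senescence. For 10 immune markers they were 3 and 3, 4 and 1, and 5 and 1, with CD68 at 0.66 ± 0.09 and 1.01 ± 0.09. For 13 pericyte and smooth muscle markers they were 6 and 5, 4 and 6, and 3 and 5, with the receptor gene NOTCH3 at 9.76 ± 1.58, 59.2 ± 24.2 and 33.7 ± 13.2 CPM in proliferating, early and late libraries. None of these last lists passed camera's test (adjusted p = 0.131 at the lowest, for immune markers in late against early senescence). The median, mean and camera direction differed in sign for endothelial, immune and pericyte markers in early senescence, for endothelial markers in late senescence, and for sensing, arrest markers, MHC class I and lysosomal genes in late against early senescence.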

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

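The tests of library depth, of evenly spread reads for the interferon and mitotic genes, of a constant ratio to MIR31HG and of the composition of proliferating libraries were chosen only after the result was seen. Among the named genes, 17 were called in opposite directions in early and late senescence against proliferating cells, and also in late against early senescence. That last call adds little. Over all tested genes, each of the 78 higher early and lower late and of the 260 lower early and higher late also had it. Some of the 17 (FGL2, PDK4, RELN, SLC14A1, S100A4, CRABP2) were among the largest late against early changes that the fixed rule picked. Their number thus does not measure how common such genes are. Higher in late than in early senescence, by log2 fold change, were MMP3 (5.37), MMP1 (3.86), CD4 (3.95), FGL2 (5.46), PDK4 (5.02), RELN (5.02), SLC14A1 (4.69), LAMA1 (3.09), LAMA4 (2.79), IFITM1 (1.93), PTGS2 (1.72), PCDHGA9 (1.39) and HMGA2 (0.947). Lower were S100A4 (−3.73, or −4.44 without late senescent replicate 1), CRABP2 (−2.88), ACTG2 (−2.34) and COL7A1 (−1.90). Some calls against proliferating cells ended without 1 library. The late call of FGL2 (0.91 on the log2 scale, here 0.55 without late senescent replicate 2 and at least 0.755 otherwise) ended without proliferating replicate 2 (adjusted p = 0.0986), 3 (0.141), late senescent replicate 2 (0.114) or 3 (0.0595), and that of PCDHGA9 (0.57, here 0.46) without proliferating replicate 1 (adjusted p = 0.059). The early call of MMP3 (−1.46, here −1.11) ended without proliferating replicate 1 (adjusted p = 0.0508), that of S100A4 (1.07, here 1.05 and 1.01) without proliferating replicate 2 (adjusted p = 0.0696) or 3 (0.0723) and that of PTGS2 (−0.53, here −0.55 to −0.39) without proliferating replicate 1 (adjusted p = 0.0907), 2 (0.11), early senescent replicate 2 (0.064), 3 (0.131) or late senescent replicate 3 (0.079). For COL7A1 the early call (0.85, here 0.48 without early senescent replicate 1 and 0.74 to 0.85 otherwise) ended without proliferating replicate 1 (adjusted p = 0.0912), 2 (0.109), early senescent replicate 1 (0.147) or late senescent replicate 1 (0.0621) and the late call (−1.05, here −0.97 and −0.91) without proliferating replicate 3 (adjusted p = 0.0539) or late senescent replicate 1 (0.0647). Scaling by library totals ended the early calls of S100A4 (adjusted p = 0.0822) and COL7A1 (0.196) and the late calls of FGL2 (0.104), PCDHGA9 (0.0827), IFITM1 (0.0777) and HMGA2 (0.199). Without a filter the early calls of S100A4 (0.0623), PTGS2 (0.0567) and COL7A1 (0.0963) and the late call of FGL2 (0.108) ended. The early PTGS2 call also ended with RLE (0.0757), upper quartile scaling (0.118), a mean of at least 1 CPM (0.0534) and DESeq2 (0.0518), the late FGL2 call with DESeq2 (0.0523), and the early calls of MMP3 (0.124) and SLC14A1 (0.0741) with limma-voom.

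Late senescent libraries had counts for more genes, although they were the smallest, and 99 genes removed by the filter had counts in all 3 late libraries and none in the other 6. Over genes with a symbol, tested or not, those with counts in all 3 libraries of a state and none in the other 6 numbered 108 for late senescent, 51 for proliferating and 6 for early senescent cells. Depth runs against the pattern, since after thinning to the smallest library the late mean was still 1436 genes above the mean of the other 6, with the largest SD of a group at 373. Reads spread evenly over the genome, as from DNA, were judged by the rate of silent olfactory receptor genes per kb of exon. At that rate 574 other silent genes would have gained counts (upper 95% bound 796), and 890 did. Without regard to exon length the shares were close, 17% of silent olfactory receptor genes and 20.1% of other silent genes. The excess thus rests on GENCODE v29 exon lengths, while the annotation used for counting is unknown, so it does not bound the share of such reads. Transcription past the end of expressed genes was tested only within 10 kb behind genes of at least 1 CPM on the same strand. There lay 28 of 937 gaining silent genes and 110 of 3777 that gained none, an odds ratio of 1.03 (95% interval 0.648 to 1.58). The interval allows a rise and longer distances were not examined, so the test cannot exclude this cause. Evenly spread reads and transcription past the end of genes stay open. So do wider transcription in late senescence and a difference in library preparation between the groups, both untested.

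The counts of IFNA1 and IFNE were higher in late senescent libraries. Evenly spread reads would give far fewer, since the late counts were at least 587 times the background set by silent olfactory receptor genes. IFNE reads taken from the overlapping MIR31HG transcript at a constant ratio would leave that ratio as in early libraries. The lowest late ratio lay 1.42 on the log2 scale above the highest early one (log2 ratios of −6.07 to −5.43 in early and −4.02 to −3.49 in late libraries). MIR31HG itself had 2688, 3121 and 2459 counts in proliferating, 1692, 1683 and 1901 in early and 2916, 4223 and 4032 in late libraries. Reads at a constant ratio could thus be part of the IFNE rise from early to late senescence, but not all of it. The ratio test was made for IFNE only, so it says nothing about IFNA1. A change in the processing of MIR31HG, reads shared among interferon alpha genes and transcription of IFNA1 and IFNE in late senescence stay open, untested.

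Mitosis genes were higher in late than in early senescence, at a median of 2.92 ± 0.10% of the proliferating level (64 genes under 5% in early libraries, SD over 3 libraries). The call of the whole list ended with an estimated correlation (adjusted p = 0.0797). Evenly spread reads are far too few, as the median gain was 492 times that of olfactory receptor genes. Added RNA with the composition of the proliferating libraries, as the whole of the median mitotic gain, would keep each of their genes at or above that gain. Of 8709 genes at 10 CPM or more in proliferating libraries, 33 lay below its lowest value, 2.07%, in each late library. Of these, 20 were histone genes, and the mitosis genes TTK, KIF18B, MYBL2 and CENPM were also among them. A smaller share of such RNA, behind part of the gain, is not excluded. RNA of dividing cells with another make-up cannot be told apart from a gain within senescent cells: the late level of histone genes lay 0.376% under the mitotic gain, with an SD of 0.383% over the late libraries. As gains over early libraries, histone genes had 0.425 ± 0.277%, mitosis genes 2.09 ± 0.02% and DNA replication genes 1.66 ± 0.14%. The low histone gain counts against such RNA only if the histone level of the senescent cells themselves did not fall from early to late senescence, which was not measured. A few cycling cells in another mix of phases, and expression of mitosis genes in arrested cells, both stay open, and no test here separates them.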

How the results depend on the processing

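Halved counts and the fit without structural RNA genes were chosen after seeing the data, and no other alternative was. Counts of changed genes stayed within 1.5 times for every alternative except 2 kinds. A test against a 1.5-fold change, which asks for more, gave 6601, 7241 and 2192 genes (early against proliferating, late against proliferating, late against early) and an overlap (genes called in both senescent states in the same direction) of 4900 against 8619, and an adjusted p of 0.01 gave 4051 for late against early. Without structural RNA genes the counts were 11014, 11420 and 6714, and leaving out 1 library gave 10045 to 11680, 10639 to 11896 and 5588 to 6752. Of the 699 named gene results, 679 kept direction and call with DESeq2, 686 with limma-voom, 688 with RLE, 647 with upper quartile scaling, 644 with library totals, 696 with halved counts and 696 without structural RNA genes. The stricter thresholds kept fewer, 638 with an adjusted p of 0.01 and 556 with the test against a 1.5-fold change. Signs turned for RTL10 in early senescence with library totals (−0.27), and for HSPA5 (0.24) in late senescence with upper quartile scaling.

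Among the lists that answer a comparison, an estimated correlation, which widens the null, ended calls for LINE-1 restriction (early 0.102, late 0.144), the secretome (0.27, 0.15, late against early 0.634), interferon-stimulated genes (late 0.442, late against early 0.634) and, in late against early senescence, type I interferon genes (0.354), mitosis (0.0797) and DNA replication (0.291). With fry, calls appeared for interferon-stimulated genes in early senescence (0.0185), arrest markers (early 6.6e-06, late 4.54e-06), type I interferon genes in late senescence (6.89e-05) and LINE-1 restriction in late against early senescence (0.0342). Library totals gave 0.0236 for interferon-stimulated genes in early senescence and 0.161 for the secretome in late against early senescence. Leaving out 1 library gave 0.0121 to 0.151 for the first, 0.00664 to 0.114 for the second and 0.0496 to 0.0862 for type I interferon genes in late senescence. All are adjusted p-values, and except where the construction is named the cause was not tested. The test with an estimated correlation also rests on the 6 residual degrees of freedom, so a lost call need not reflect correlation between genes. The p53 targets, at an estimated correlation of 0.019, went from 8.86e-10 to 0.0126 in early senescence and kept their call.

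With the replicate number as a replicate block, 11730, 12105 and 8256 genes were called, with an overlap of 9126, and no call of these lists changed. In late against early senescence the block gave 3851 genes higher and 4405 lower, against 3572 and 3314 without it. The numbers were not taken as pairing the libraries. Of 9 same-numbered pairs, 4 had a correlation of deviations over 0.1 (range −0.1 to 0.31). The 3 of 9 libraries that correlated best with their own number in both other groups were those of replicate 3. Their pairs had 0.18, 0.3 and 0.31. Pairs with different numbers had −0.33 to 0.23. Some libraries of different states thus shared deviations, which the main fit does not model. Of the 10 splits of the 6 libraries in each comparison, 1 called as many genes as the real split, itself (11123, 11537 and 6886). The highest other called 0. Every other split put libraries of both states on each side, so the difference between states entered the spread and few calls could arise. In addition, 10 splits cannot give a share under 0.1. Depth limits the interferon ligands other than IFNA1 and IFNE, which held at most 1 count in a proliferating or early senescent library.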

Other observations

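Clustered protocadherins, cell surface adhesion genes arranged in tandem clusters, mostly rose in senescence. Of 47, 35 rose and 5 fell in early senescence, with a median log2 fold change of 2.50 (camera adjusted p = 2.26e-06, adjusted p = 0.0439 with an estimated correlation), and 42 rose and 3 fell in late senescence, with a median of 2.82 (camera adjusted p = 3.97e-10, adjusted p = 0.012 with an estimated correlation). In late against early senescence 25 rose and 2 fell (camera adjusted p = 0.000146, adjusted p = 0.201 with an estimated correlation). PCDHB2 rose by 4.01 ± 0.34 in early and 5.56 ± 0.35 in late senescence on the log2 scale. PCDHGA4 went from 1.36 ± 0.280 to 10.4 ± 1.17 and 10.2 ± 0.941 CPM. Genes of the gamma cluster share their last exons, as do genes of the alpha cluster, so counts within each are not separate. HOX genes and transcription factors of lung mesenchyme had 1 higher and 22 lower of 28 in early senescence, with a median of −1.50 (camera adjusted p = 6.88e-06, adjusted p = 0.075 with an estimated correlation), 1 and 17 in late senescence, with a median of −0.72 (camera adjusted p = 0.00153, adjusted p = 0.164 with an estimated correlation), and 16 and 2 in late against early senescence (camera adjusted p = 0.00105, adjusted p = 0.291 with an estimated correlation). TCF21, a transcription factor of lung mesenchyme, fell by 3.21 ± 0.21 on the log2 scale in early senescence, and TBX2 fell by 6.35 ± 0.69.

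ERV-derived and other retroelement-derived genes went both ways, with 5 higher and 12 lower of 26 in early senescence, 4 and 9 in late senescence and 7 and 4 in late against early senescence (camera adjusted p = 0.221, 0.358 and 0.226). Their late median of −0.13 became 0.15 with upper quartile scaling. PEG10, a gene derived from a retrotransposon, was at −3.56 ± 0.12 in early and −2.72 ± 0.11 in late senescence, and ERV3-1 at 0.98 ± 0.14 and 1.43 ± 0.14. Pluripotency markers had 0 higher and 3 lower of 5 in early, 1 and 2 in late and 2 and 0 in late against early senescence (camera adjusted p = 0.233, 0.723 and 0.168); the late median of −0.06 became 0.02 with RLE and 0.23 with upper quartile scaling. Germline genes had 0 and 0 of 3, 1 and 1, and 1 and 0 (camera adjusted p = 0.772, 0.723 and 0.469), with a late median of 0.02 that became −0.18 with library totals. The member that rose was CTAG2, a cancer-testis antigen chosen here after its values were seen, with 64, 26 and 66 counts in late libraries and 0 counts in the other 6.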
